A study of Arabidopsis thaliana with 148 samples.

How the data were processed

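Total mRNA and TRAP mRNA of Arabidopsis seedlings were read from 2 deposited tables of raw counts per gene, 1 for the time course (100 libraries) and 1 for the recovery experiment (48 libraries), each with 38194 genes. Per the labels' protocols, polyadenylated RNA was isolated with biotinylated oligo(dT) beads and libraries were amplified with PCR; no molecular identifiers are named, so counts are of reads. Per the submitters' processing notes the authors used cutadapt, FastQC and HISAT2 2.2.0 with the TAIR10 genome. The counting tool, the annotation and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and the authors' counting may have divided reads between near-identical family members. The values were whole counts that summed to different totals per library, as the authors deposited them. Of the gene identifiers, 37751 matched the RefSeq table of assembly TAIR10.1, which was used for gene symbols and for which genes overlap.

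Samples were grouped by kind of RNA, time and treatment from the labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries scaled by TMM, and group means fitted with a robust quasi-likelihood model over all libraries of an experiment and kind of RNA, or of both kinds for the difference between them. Each comparison was a two-sided quasi-likelihood test with Benjamini-Hochberg adjustment, called at an adjusted p below 0.05. The heat effect by time of day was an F test with 7 degrees of freedom, and rhythms were tested with a cosine and a sine of period 24 h. Fold changes are log2 with their standard errors, and a log2 CPM used a prior count of 2. Gene lists, 18 with 325 members, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation: heat shock factors, small heat shock proteins, large chaperones, circadian clock, B-box and CDF transcription factors, light harvesting and Rubisco, cytosolic ribosomal proteins, ribosome biogenesis, endoplasmic reticulum folding, reactive oxygen scavenging, cold and dehydration, abscisic acid, rapid stress transcription factors, jasmonate, PIF and auxin growth, starch degradation, aliphatic glucosinolate synthesis and root markers.

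Genes were named by a rule fixed before the data were examined. It took members of the heat shock factor, small heat shock protein, large chaperone and clock lists (13 fixed genes and the 3 largest changes), up to 4 called members with the largest change of each other list, the 10 highest and 10 lowest genes of each mean comparison with a mean log2 CPM of at least 1, the 3 highest and 3 lowest of each single comparison in which every heat library lay beyond every control, the 8 smallest p-values of each test over times, and RPL18B because the tag is on RPL18. From these, genes without counts in a group of the comparison were left out of the text. RPA70D, FMOGS-OX1, GSTF11 and AT5G10390, given as means over times, had 3 or fewer counts in 6, 3, 3 and 2 of the 16 groups of total mRNA.

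Alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts (minimum count 1), the replicate number as a block, only the 2 groups compared, rhythms over ZT48 to ZT69 only, an estimated correlation or fry for the lists, and leaving out each replicate in turn. After the data were seen, 4 more were added: leaving out libraries in doubt of the recovery experiment or of the time course, leaving out organelle genes, and thinning each library at random, by binomial draws, to the smallest total of its kind of RNA. Thinning was first run with the thinCounts function of edgeR, which raised the common dispersion of the total mRNA libraries from 0.0136 to 0.177; binomial draws gave 0.0145 to 0.0146 and replaced it after its values were seen.

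The tests were run on simulated counts, drawn from the mean of each gene over controls, the scaled library sizes and the trended spread. Among genes above a low level 100 were changed 2-fold and 100 changed 4-fold, as many up as down. Real heat changed far more genes, so scaling and recovery under such a broad response were not tested. Of these, the tests recovered, at 2-fold and at 4-fold, 82 and 99 of 100 for heat at ZT48 in total mRNA (20493 genes), 82 and 100 of 100 for heat at ZT48 in TRAP mRNA (19891 genes), 100 and 100 of 100 for the mean heat effect in total mRNA (20651 genes) and 100 and 100 of 100 for the mean heat effect in TRAP mRNA (19858 genes). They recovered 57 and 93 of 100 for heat by time of day in total mRNA (20493 genes), 66 and 97 of 100 for heat by time of day in TRAP mRNA (19891 genes), 92 and 100 of 100 for rhythms of total mRNA controls (20663 genes), 98 and 100 of 100 for rhythms of TRAP controls (20593 genes), 71 and 98 of 100 for the rhythm difference in total mRNA (20655 genes) and 79 and 100 of 100 for the rhythm difference in TRAP mRNA (19830 genes). In recovery they recovered 74 and 98 of 100 for recovery at 0 h in total mRNA (20050 genes), 70 and 96 of 100 for recovery at 0 h in TRAP mRNA (20026 genes), 39 and 93 of 100 for the 6 h against the 0 h effect in total mRNA (20050 genes) and 42 and 90 of 100 for the 6 h against the 0 h effect in TRAP mRNA (20026 genes). Between the fractions they recovered 62 and 96 of 100 for TRAP against total mRNA at ZT48 (20910 genes), 99 and 100 of 100 for TRAP against total mRNA over the day (20875 genes) and 43 and 91 of 100 for TRAP against total mRNA at 0 h of recovery (20713 genes). With a rhythm simulated in controls alone, 0 rhythms were called in the heat libraries (19327 and 18694 genes). Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 1.71 over 146 pairs, so none was counted as a copy. Whether same-numbered libraries deviate together from their group means was checked for each comparison by the correlation over genes. For total against TRAP mRNA every pair lay above 0.1 at ZT51, ZT54, ZT63 and 1 h of recovery, and the numbers were taken to pair the libraries there, from the data and not from the labels.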

Results

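The series measured messenger RNA in Arabidopsis thaliana seedlings that carry an epitope-tagged ribosomal protein L18 (RPL18) under the 35S promoter. The tag allows ribosomes to be pulled down with the messages on them, a method called translating ribosome affinity purification (TRAP). Polyadenylated RNA was sequenced from whole seedlings (total mRNA, the transcriptome) and from the purified ribosomes (TRAP mRNA, the translatome). Seedlings grew for 10 days in cycles of 12 h light and 12 h dark at 22 °C and went into constant light on day 11. On day 13 separate sets of seedlings received 1 h at 37 °C ending at 1 of 8 times of day, from Zeitgeber time (ZT) 48, the subjective dawn, to ZT69 in steps of 3 h. Controls stayed at 22 °C and were taken from ZT48 to ZT72. A second experiment applied the 1 h of heat before ZT54 and returned seedlings to 22 °C for 0, 1, 3 or 6 h, each with time-matched controls. The 148 libraries fell into 50 groups, 48 of 3 replicates and 2 of 2 (total mRNA control at ZT57 and TRAP control at ZT60). Total counts per library ran from 1396305 to 13706459 in the time course (median 7158394) and from 3080248 to 8745785 in the recovery experiment (median 6081310). Depth was uneven over the day. Total mRNA libraries had a median of 8873006 counts at ZT48 to ZT57 (n = 23) and 4123844 at ZT60 to ZT72 (n = 27), and TRAP libraries 9398937 (n = 24) and 5902330 (n = 26). The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

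The first comparison asked which transcripts of the whole seedling respond to 1 h at 37 °C, averaged over the 8 times of day (24 heat and 23 control libraries). Chaperone transcripts dominated the response. All 16 small heat shock protein genes rose, whose products bind unfolding proteins, with a median log2 fold change of 9.92 (16 up adjusted over the list alone, camera adjusted p = 3.11e-11, and adjusted p = 0.0790 with an estimated correlation). Class II HSP17.6-CII (AT5G12020) rose by 10.03 ± 0.45 (log2 fold change ± SE), the chloroplast protein gene HSP21 (AT4G27670) by 10.03 ± 0.34 and class I HSP17.6B-CI (AT2G29500) by 9.40 ± 0.38. All 28 large chaperone genes rose as well, with a median of 4.99 (28 up adjusted over the list alone, camera adjusted p = 4.77e-22). They included the disaggregase HSP101 (AT1G74310) at 8.74 ± 0.28, HSP90.1 (AT5G52640) at 9.03 ± 0.33, HSP70-4 (AT3G12580) at 8.001 ± 0.24 and the FKBP-type immunophilin ROF2 (AT5G48570) at 9.43 ± 0.38. Among these genes the adjusted p reached at most 8.10e-21 for HSP17.6-CII (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The 44 genes of both chaperone lists took 13.69% ± 1.77 (SD, n = 24) of the counts of a heat library and 0.212% ± 0.119 (SD, n = 26) of a control library. Some control libraries held a trace of the heat-induced transcripts. Over 117 such genes, the median was 2.18% of the heat level in total mRNA control replicate 2 at ZT54 and 0.316% and 0.120% in replicates 1 and 3 at ZT48. Folds of chaperone genes at those times are against such controls: HSP101 at ZT54 stood at 6.63 ± 0.66, and at 9.45 without control replicate 2. Members of these families share sequence, so reads may have been divided between near-identical copies, and the locus AT3G07365 lies within HSP17.4-CI (AT3G46230) in the RefSeq annotation and cannot be told from it. Other annotated genes likewise overlap HSP101 and several genes named further on (MBF1C, DREB2A, ERDJ3A, GSTF11, RCA, LHCB2.3, LHCB3, LNK1, LNK4, CBF3 and EGY3).

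Among regulators of the heat response some genes rose and others fell. Among 21 heat shock factors, the transcription factors that bind heat shock elements, 12 rose, 7 fell and 2 did not pass the test (12 up and 7 down adjusted over the list alone, camera adjusted p = 5.12e-04). HSFA2 (AT2G26150), which sustains acquired thermotolerance, rose by 9.68 ± 0.31, HSFA7A (AT3G51910) by 6.12 ± 0.080 and the class B factor HSFB1 (AT4G36990) by 5.13 ± 0.058. In the list of rapid stress transcription factors 9 rose and 3 fell (9 up and 3 down adjusted over the list alone, camera adjusted p = 0.00120). It was led by the coactivator MBF1C (AT3G24500) at 7.78 ± 0.21, the dehydration-responsive DREB2A (AT5G05410) at 5.50 ± 0.060 and the zinc finger gene ZAT12 (AT5G59820) at 4.59 ± 0.076. Of 17 endoplasmic reticulum folding genes 16 rose and 1 did not pass the test (16 up adjusted over the list alone, camera adjusted p = 2.31e-11). TIN1 (AT5G64510) stood at 8.49 ± 0.13, the DnaJ co-chaperone ERDJ3A (AT3G08970) at 8.08 ± 0.17 and the BiP chaperone gene BIP1 (AT5G28540) at 3.95 ± 0.058. Of 9 genes that remove reactive oxygen species 7 rose and 2 fell (7 up and 2 down adjusted over the list alone, camera adjusted p = 0.0117). APX2 (AT3G09640), a cytosolic ascorbate peroxidase, rose by 10.20 ± 0.28 and APX1 (AT1G07890) by 1.97 ± 0.043. In the abscisic acid list 8 rose (8 up adjusted over the list alone, camera adjusted p = 1.55e-05). NCED3 (AT3G14440), which encodes an enzyme of abscisic acid synthesis, rose by 2.98 ± 0.087. The adjusted p of the genes named here was at most 4.21e-25 for HSFA2 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

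Other transcripts fell. All 12 genes of aliphatic glucosinolate synthesis, which makes sulfur-rich defence compounds, were lower (12 down adjusted over the list alone, camera adjusted p = 3.01e-07). The flavin monooxygenase gene FMOGS-OX1 (AT1G65860) stood at -4.33 ± 0.15, the sulfotransferase gene SOT17 (AT1G18590) at -3.35 ± 0.10 and the C-S lyase gene SUR1 (AT2G20610) at -2.82 ± 0.056. Among the 10 lowest genes were GSTF11 (AT3G03190), a glutathione S-transferase, at -4.99 ± 0.14, the histone H3 gene AT5G10390 at -4.70 ± 0.13 and RPA70D (AT5G61000), a replication protein A subunit, at -4.42 ± 0.19. Over the 12 genes of the PIF and auxin growth list 9 rose, 1 fell and 2 did not pass the test (9 up and 1 down adjusted over the list alone, camera adjusted p = 0.0113), and PIF4 (AT2G43010), a basic helix-loop-helix factor of thermal growth, rose by 2.48 ± 0.064. Of the light harvesting and Rubisco genes 19 rose, 3 fell and 3 did not pass the test (19 up and 3 down adjusted over the list alone, camera adjusted p = 4.03e-04, and adjusted p = 0.237 with an estimated correlation). They included RCA (AT2G39730), Rubisco activase, at 1.22 ± 0.047 and LHCB2.3 (AT3G27690) at -1.33 ± 0.077. Members of the other lists went both ways. Among 42 cytosolic ribosomal protein genes 15 rose, 17 fell and 10 did not pass the test (15 up and 17 down adjusted over the list alone, camera adjusted p = 0.938). Their median was 0.011 and their mean -0.035, and the median was -0.043 with RLE scaling, -0.044 with DESeq2 and -0.0042 without a filter. For ribosome biogenesis 7 rose, 7 fell and 5 did not pass the test (7 up and 7 down adjusted over the list alone, camera adjusted p = 0.635), with a median of -0.080 and a mean of 0.027. For the cold and dehydration list 6 rose, 2 fell and 2 did not pass the test (6 up and 2 down adjusted over the list alone, camera adjusted p = 0.0448, and adjusted p = 0.413 with an estimated correlation), led by the dehydrin COR47 (AT1G20440) at 3.09 ± 0.046. For jasmonate 1 rose, 4 fell and 1 did not pass the test (1 up and 4 down adjusted over the list alone, camera adjusted p = 0.391). For starch degradation 7 rose, 2 fell and 4 did not pass the test (7 up and 2 down adjusted over the list alone, camera adjusted p = 0.315), and for root markers 2 rose, 4 fell and 2 did not pass the test (2 up and 4 down adjusted over the list alone, camera adjusted p = 0.547). No gene named here had an adjusted p above 7.16e-18 for LHCB2.3 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

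Across all tested genes, 17138 of 21234 differed on average over the day in total mRNA, 7826 up and 9312 down (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p below 0.05). At the single times from ZT48 to ZT69 the numbers were 12280, 11995, 10942, 10674, 10109, 9365, 9345 and 9083 (3 heat libraries against 3 controls, 2 at ZT57). With all total mRNA libraries reduced at random to the smallest total, 1396305, the same 8 times gave 5791, 5555, 5424, 4861, 5864, 6118, 5375 and 5421, so the decline over the day went with depth. Over the day 3101 genes rose at all 8 times, 2153 fell at all 8 and 17022 were called at 1 time or more, of which 134 rose at 1 time and fell at another.

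**Figure D1:**
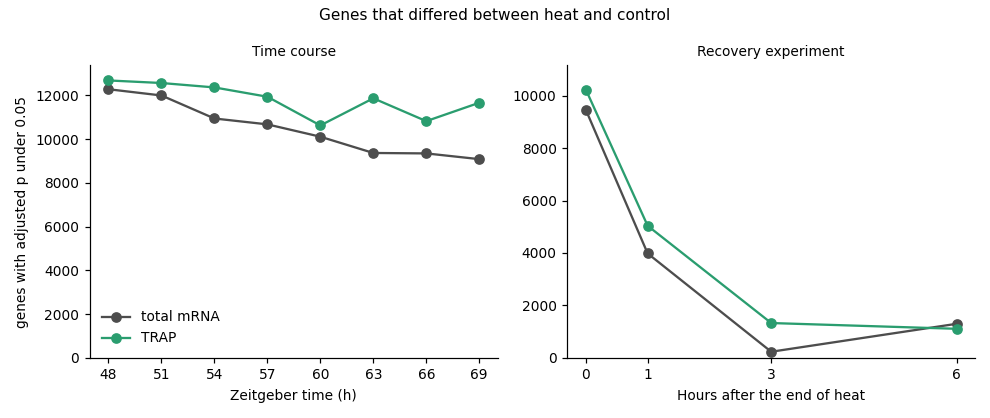
Genes with an adjusted p below 0.05 in heat against control, by Zeitgeber time in hours (left) and by hours of recovery after heat (right), with 1 line for total mRNA and 1 for TRAP mRNA. Each point is 1 comparison of a heat group with its time-matched control, at the library totals as deposited.

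The second question was whether the heat effect itself depends on time of day, tested as an interaction over the 8 times. Clock genes and their relatives were among the genes with the smallest p. The pseudo-response regulator PRR7 (AT5G02810), which represses the morning genes, rose least at ZT54, 1.82 ± 0.13, and most at ZT66, 5.40 ± 0.19 (adjusted p = 6.11e-27 for the interaction). The night-light-inducible clock gene LNK1 (AT5G64170) ran from 2.05 ± 0.12 at ZT51 to 5.11 ± 0.17 at ZT66 (adjusted p = 5.68e-26). The B-box gene COL5 (AT5G57660) ran from 0.76 ± 0.12 at ZT54 to 3.85 ± 0.18 at ZT66 (adjusted p = 1.44e-24) and PIF4 from 1.00 ± 0.14 to 5.26 ± 0.26 at the same times (adjusted p = 5.40e-19). GI (AT1G22770) (GIGANTEA), a clock gene of the evening, was at 0.34 ± 0.17 at ZT57, short of the threshold, and at 2.39 ± 0.24 at ZT69. For LHY (AT1G01060), a morning MYB factor, the interaction was not called in total mRNA (adjusted p = 0.780), and its fold lay between -0.80 and -0.42. These p-values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of 28 clock genes 19 had a heat effect that varied with time (21 adjusted over the list alone). So did 11 of 29 B-box and CDF factors (19 adjusted over the list alone) and 13 of 25 light harvesting and Rubisco genes (13 adjusted over the list alone).

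Some light harvesting genes responded in the subjective night. LHCB2.2 (AT2G05070), a photosystem II antenna gene, stood at 2.14 ± 0.20 at ZT63 and 1.57 ± 0.18 at ZT66 and was not called at the other 6 times (adjusted p = 1.58e-09 for the interaction, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). LHCB3 (AT5G54270) stood at 1.99 ± 0.14 and 1.57 ± 0.13 at these times. Cold response genes varied in part, 6 of 10 (6 adjusted over the list alone), and the transcription factor gene CBF3 (AT4G25480) fell by 2.35 ± 0.44 at ZT57. Of 42 ribosomal protein genes 1 varied with time, and of 19 ribosome biogenesis genes 0 (3 at an unadjusted p below 0.05, edgeR quasi-likelihood test). In all, 767 of 21234 genes in total mRNA and 1484 of 21079 in TRAP mRNA had a time-dependent heat effect. With 1 replicate number left out the counts fell to between 318 and 450 in total mRNA and between 502 and 1158 in TRAP mRNA, and without a filter on low counts they were 1408 and 2661. Because depth differed between the first and the last times, the test was repeated within each depth block. In total mRNA 347 genes were called within ZT48 to ZT57 and 96 within ZT60 to ZT69, and 352 of the 767 were called in either block. In TRAP mRNA the numbers were 708, 199 and 717 of 1484.

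Rhythms were then fitted as a 24 h cosine wave, in controls over ZT48 to ZT72 and in heat-treated seedlings over ZT48 to ZT69. Each heat point is a separate set of seedlings taken at the end of 1 h of heat, and none was followed over a cycle. A wave after heat thus reflects the heat effect at each time, as in the interaction test, and not a later rhythm. Over the heat libraries the waves of several clock and growth genes were flatter than in controls. The amplitude of PRR7, as log2, was 2.22 in controls and 0.49 after heat (adjusted p = 2.41e-14 for the difference). For LNK1 it was 1.72 and 0.31 (adjusted p = 8.69e-12), and for GI 1.32 and 0.23 (adjusted p = 1.66e-11). PIF5 (AT3G59060) went from 1.67 to 0.37 (adjusted p = 1.19e-16) and CDF1 (AT5G62430), a repressor of flowering, from 1.30 to 0.36 (adjusted p = 2.73e-12). CCA1 (AT2G46830), the MYB partner of LHY, had a wave of 1.29 after heat against 2.05 in controls (adjusted p = 9.91e-10). For LHY the amplitudes were 2.098 and 2.13 (adjusted p = 0.996 for the difference), and for the evening gene TOC1 (AT5G61380) 1.14 and 1.12 (adjusted p = 0.137), neither called. All of these p-values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of 28 clock genes 26 cycled in total mRNA controls and 27 after heat, and 17 differed between them. All 12 glucosinolate genes cycled in controls. A rhythm was called for 10671 of 20811 genes in total mRNA controls and 8832 of 18326 after heat, and 1026 of 21521 differed in rhythm. In TRAP mRNA the counts were 12893 of 20856, 10222 of 18027 and 1785 of 21064. With 1 replicate number left out, 320 to 433 genes differed in rhythm in total mRNA and 609 to 819 in TRAP mRNA. A single day was sampled, so a 24 h wave cannot be told from a drift over that day. Library depth also differed between ZT48 to ZT57 and ZT60 to ZT72, and a step between these blocks would add to such a wave. Rhythms were not tested within the blocks. Control groups 24 h apart, ZT72 and ZT48, lay in different blocks and differed in 2704 genes in total mRNA and 2073 in TRAP mRNA. Of the small heat shock proteins, 11 of 16 were called rhythmic in total mRNA controls and 0 in TRAP controls, and the total mRNA control with the highest trace of heat-induced transcripts lay at ZT54.

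**Figure D2:**
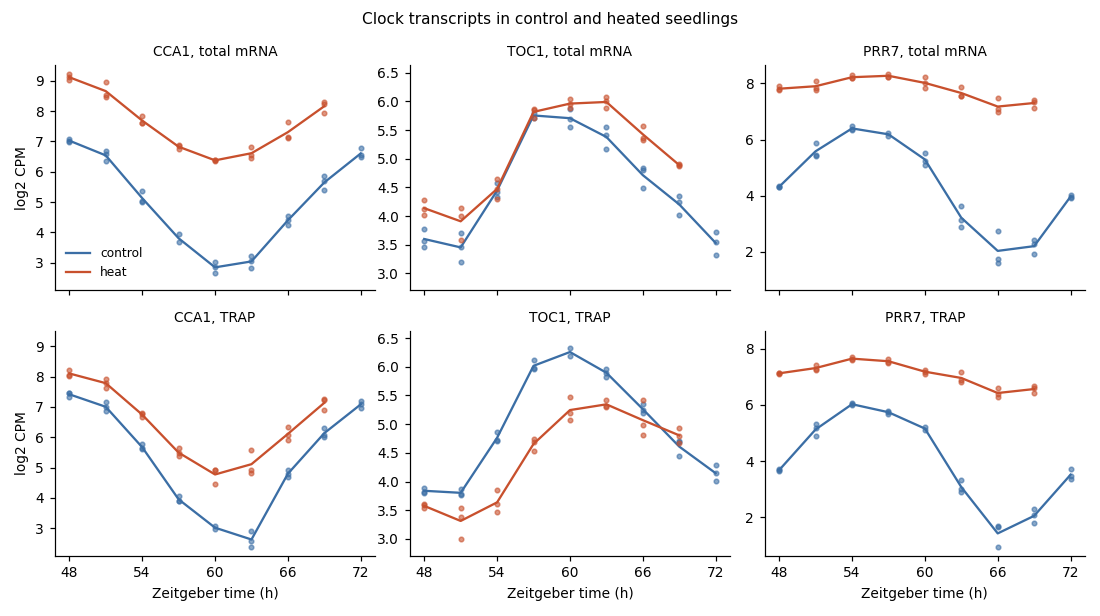
Expression of CCA1, TOC1 and PRR7 as log2 CPM against Zeitgeber time in hours, in total mRNA and TRAP mRNA. Each point is 1 library and lines join group means, for controls from ZT48 to ZT72 and heat-treated seedlings from ZT48 to ZT69.

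In TRAP mRNA the ribosome-bound messages answered heat much as total mRNA did. The 28 large chaperones all rose (28 up adjusted over the list alone, camera adjusted p = 6.70e-21). Of the small heat shock proteins 15 rose and 1 fell (15 up and 1 down adjusted over the list alone, camera adjusted p = 3.94e-09, and adjusted p = 0.124 with an estimated correlation), the exception being HSP15.4 (AT4G21870) at -0.49 ± 0.11. HSFA2 rose by 10.75 ± 0.40, HSP101 by 9.73 ± 0.34, HSP21 by 11.38 ± 0.41 and TIN1 by 8.98 ± 0.13, while FMOGS-OX1 was at -3.85 ± 0.097 and AT5G10390 at -5.15 ± 0.15. Chaperone lists took 24.8% ± 1.23 (SD, n = 24) of TRAP counts after heat and 0.310% ± 0.0791 (SD, n = 26) in controls. All 12 glucosinolate genes fell (12 down adjusted over the list alone, camera adjusted p = 5.12e-06). Among heat shock factors 13 rose, 5 fell and 2 did not pass the test (13 up and 5 down adjusted over the list alone, camera adjusted p = 4.24e-04). Of the starch degradation genes 11 rose and 2 fell (11 up and 2 down adjusted over the list alone, camera adjusted p = 0.00744, and adjusted p = 0.136 with an estimated correlation), with the beta-amylase gene BAM1 (AT3G23920) at 3.10 ± 0.058. For light harvesting and Rubisco 21 rose, 1 fell and 3 did not pass the test (21 up and 1 down adjusted over the list alone, camera adjusted p = 3.43e-05, and adjusted p = 0.143 with an estimated correlation). The adjusted p of the named genes was at most 7.27e-05 for HSP15.4 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). On average over the day 17629 of 21079 genes differed, 8039 up and 9590 down, and at the 8 single times 12682, 12565, 12363, 11937, 10624, 11866, 10821 and 11662. Of the 20391 genes tested in both kinds of RNA, 6600 rose in both, where independent lists would share 2979.9, and 7727 fell in both, against 4029. Across these genes, which are not independent replicates, the mean heat effects correlated with Pearson r = 0.952 and Spearman rho = 0.911, and 595 genes were called in opposite directions.

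The difference between the TRAP and the total mRNA heat effect was tested gene by gene. Libraries were scaled by TMM, so a shift of most messages onto or off ribosomes would not be seen. A difference is relative to the other genes, and higher or lower below refers to the heat effect and not to a level. The list counts below keep organelle genes in the scaling and are not given without them. Leaving these genes out moved the direction of the majority of all called genes, as the next paragraph gives. The heat effect on the clock genes CCA1 and TOC1 was lower in TRAP than in total mRNA. For CCA1 the difference was -1.43 ± 0.073 (heat effect 2.80 in total and 1.35 in TRAP mRNA), and for TOC1 -1.001 ± 0.065 (0.43 and -0.60). The abscisic acid list stood lower in TRAP mRNA, 2 higher and 6 lower of 8 (2 and 6 adjusted over the list alone, camera adjusted p = 0.00337, and adjusted p = 0.212 with an estimated correlation), with NCED3 at -0.85 ± 0.11 and the phosphatase gene ABI2 (AT5G57050) at -0.67 ± 0.077. Most large chaperones stood higher, 20 higher and 3 lower of 28 (21 and 3 adjusted over the list alone, camera adjusted p = 1.29e-04, and adjusted p = 0.569 with an estimated correlation). HSP101 was at 1.00 ± 0.31 and HSP70-16 (AT1G11660) at -1.02 ± 0.086. The call of HSP101 was lost without replicate 1 or without replicate 3, in fits with fewer samples that left it at 0.95 and 0.90. Starch degradation had 10 higher and 0 lower of 13 (12 and 0 adjusted over the list alone, camera adjusted p = 0.00105, and adjusted p = 0.212 with an estimated correlation). Light harvesting had 11 higher and 0 lower of 25 (12 and 0 adjusted over the list alone, camera adjusted p = 0.0111, and adjusted p = 0.595 with an estimated correlation). Rapid stress factors had 7 higher and 0 lower of 13 (7 and 0 adjusted over the list alone, camera adjusted p = 0.0390, and adjusted p = 0.212 with an estimated correlation), with ZAT12 at 1.05 ± 0.12. Among the 10 highest and 10 lowest single genes were EGY3 (AT1G17870) at 1.98 ± 0.14, the xyloglucan endotransglucosylase gene XTH18 (AT4G30280) at 1.91 ± 0.19, the homeodomain gene PHV (AT1G30490) at -2.19 ± 0.085 and the purple acid phosphatase gene PAP28 (AT5G57140) at -2.03 ± 0.15. Among these genes the adjusted p was at most 0.00685 for HSP101 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). For RPL18B (AT3G05590), a gene of the tagged protein's family, the heat effect was 0.48 ± 0.073 higher in TRAP mRNA. Its adjusted p was 3.62e-08 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Reads of a transgene copy could not be told from those of RPL18B.

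Over all genes, 7928 of 22256 differed in heat effect between the fractions on average, 4783 higher in TRAP mRNA and 3145 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The share called higher in TRAP mRNA, 60.3%, was 45.6% once chloroplast and mitochondrial genes were left out before scaling, so the direction of the majority is not settled. Chloroplast genes took 26.49% of total mRNA counts and 0.330% of TRAP counts in controls. At single times from ZT48 to ZT69 1396, 652, 956, 1023, 702, 588, 434 and 365 genes differed in the fit without a replicate block. At the lowest these were 340, 231, 291, 268, 210, 170, 130 and 76 with 1 replicate number left out. With the replicate number as a block the counts were 1289 at ZT51, 1793 at ZT54 and 1037 at ZT63, the times at which every pair of total and TRAP libraries lay above 0.1. The numbers may pair these libraries at other times too, and the counts with a block there are given further on. Without organelle genes the share higher in TRAP mRNA moved in the fit without a block, from 51.1% to 36.2% at ZT48, 38.0% to 27.5% at ZT51, 42.7% to 29.7% at ZT54 and 40.96% to 27.8% at ZT57. It moved from 37.2% to 23.4% at ZT60, 50.7% to 29.8% at ZT63, 35.3% to 24.7% at ZT66 and 44.4% to 21.8% at ZT69, where the median of all genes shifted by -0.11. With RLE scaling it was 38.8% at ZT63 and 29.9% at ZT69, and with DESeq2 39.6% and 31.8%. Without a filter on low counts it was 37.2% at ZT48, and without the controls that held heat-induced transcripts 35.2% at ZT48 and 32.7% at ZT69. The heat effect on CCA1 and TOC1 was lower in TRAP mRNA on average with RLE scaling, with DESeq2, without a filter and without organelle genes.

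**Figure D3:**
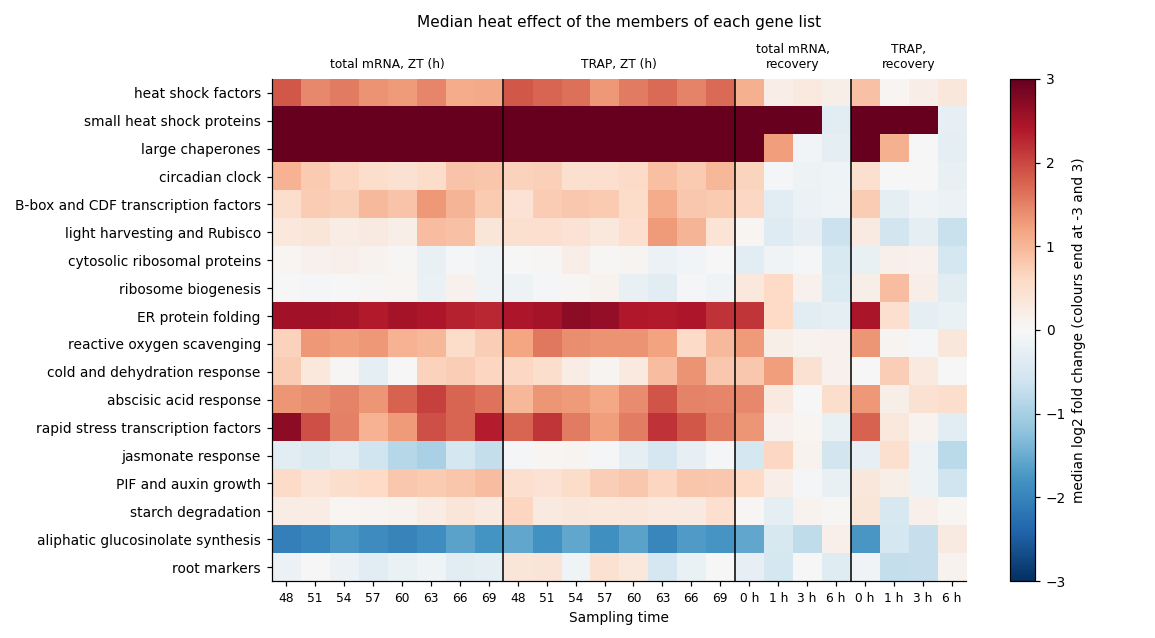
Median log2 fold change of the members of 18 gene lists (vertical axis) in each comparison (horizontal axis), as a colour scale that ends at -3 and 3. Small heat shock proteins and large chaperones lie beyond the upper end of the scale in the heat comparisons.

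The recovery experiment began with a repeat of the ZT54 heat treatment in other libraries. Directly after heat, all 28 large chaperones and all 16 small heat shock protein genes rose in total mRNA, 28 and 16 adjusted over the list alone (camera adjusted p = 1.77e-30 for the former and camera adjusted p = 9.34e-19 for the latter). HSP101 stood at 9.29 ± 0.34, HSP17.6B-CI at 10.21 ± 1.21, HSP70-4 at 8.46 ± 0.40 and HSP90.1 at 10.37 ± 0.31. The 12 glucosinolate genes fell (12 down adjusted over the list alone, camera adjusted p = 2.73e-09). Ribosomal protein genes fell in part: 22 fell and 20 did not pass the test (22 down adjusted over the list alone, camera adjusted p = 0.00107, and adjusted p = 0.529 with an estimated correlation). CCA1 rose by 2.64 ± 0.19 in total mRNA and by 0.82 ± 0.16 in TRAP mRNA. The named genes had adjusted p-values of at most 1.09e-04 for CCA1 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In all 9462 of 20503 genes differed in total mRNA (4698 up, 4764 down) and 10236 of 20504 in TRAP mRNA (5051 up, 5185 down). Of the genes called at ZT54 in the time course, 95.4% of 10621 lay on the same side of 0 here in total mRNA and 94.7% of 12120 in TRAP mRNA, called here or not. Called in the same direction were 7383 and 8219, and in the opposite direction 25 and 36. Across genes, which are not independent replicates, Pearson r was 0.885 and 0.884 and Spearman rho 0.844 and 0.847.

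After 1 h back at 22 °C most chaperone genes were still raised and other groups moved. In total mRNA 15 of 16 small heat shock proteins rose (15 adjusted over the list alone, camera adjusted p = 6.78e-26) and 19 of 28 large chaperones (22 adjusted over the list alone, camera adjusted p = 3.66e-20). HSP17.6B-CI stood at 7.77 ± 1.11, HSP90.1 at 6.08 ± 0.28 and HSP101 at 3.04 ± 0.30. Most ribosome biogenesis genes, which process ribosomal RNA and assemble subunits, rose. In total mRNA 12 rose and 6 did not pass the test (14 up adjusted over the list alone, camera adjusted p = 1.44e-08, and adjusted p = 0.154 with an estimated correlation), and in TRAP mRNA 16 rose and 3 did not pass the test (17 up adjusted over the list alone, camera adjusted p = 6.81e-13), including APUM24 (AT3G16810) at 1.56 ± 0.21 and 1.66 ± 0.19. Part of the light harvesting and Rubisco genes fell, 9 of 25 in total mRNA (12 adjusted over the list alone, camera adjusted p = 8.59e-07, and adjusted p = 0.204 with an estimated correlation) and 19 of 25 in TRAP mRNA (22 adjusted over the list alone, camera adjusted p = 9.02e-12). Part of the starch degradation genes fell in TRAP mRNA, 7 of 13 (10 adjusted over the list alone, camera adjusted p = 1.92e-05). LHY fell by 2.299 ± 0.41 in total mRNA. No named gene had an adjusted p above 7.61e-04 for LHY (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). At 1 h 3981 genes differed in total mRNA (2005 up, 1976 down) and 5038 in TRAP mRNA (2457 up, 2581 down). Without the TRAP 3 h control replicate 1 and 6 h control replicate 2 libraries, which share the estimate of spread, the TRAP count was 7642.

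By 3 h part of the small heat shock protein genes were still raised. In total mRNA 8 rose and 8 did not pass the test (14 up adjusted over the list alone, camera adjusted p = 5.05e-29), and in TRAP mRNA 13 rose and 3 did not pass the test (14 up and 1 down adjusted over the list alone, camera adjusted p = 7.79e-19, and adjusted p = 0.0798 with an estimated correlation). HSP17.6B-CI stood at 5.59 ± 1.06 in total mRNA, HSP90.1 at 1.79 ± 0.34 and HSP70-4 at 1.52 ± 0.36. HSP70-4 was no longer called when any 1 of the 6 libraries was left out. The same held for HSP17.6B-CI without any 1 of the controls or heat replicate 2, and for HSP90.1 without control replicate 2. In these fits with fewer samples the folds ran from 1.33 to 1.74 for HSP70-4 and 5.41 to 5.72 for HSP17.6B-CI. For HSP90.1 they ran from 1.47 to 1.985. The estimate of spread at 3 h also takes in the library labelled 6 h control replicate 2, which correlated best with the 3 h heat group. A high spread of heat-induced genes among the 6 h controls would widen the errors at 3 h. The lost calls therefore do not show a smaller effect. LHY fell furthest of the 28 clock genes, by 4.14 ± 0.67 in total mRNA and 3.79 ± 0.45 in TRAP mRNA. Glucosinolate genes were still lower, 5 of 12 in total mRNA (8 adjusted over the list alone, camera adjusted p = 1.01e-09, and adjusted p = 0.0533 with an estimated correlation). Named genes had an adjusted p of at most 0.0491 for HSP70-4 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In total mRNA 229 genes differed (103 up, 126 down) and in TRAP mRNA 1325 (462 up, 863 down). Single libraries moved these counts, to 78 in total mRNA without heat replicate 2, and in TRAP mRNA to 293 without heat replicate 2 and 3848 without control replicate 2. The TRAP 3 h control replicate 1 library stood apart, with RPL18B at 10.6 log2 CPM where the mean of the 24 TRAP libraries was 12.5, and without it the TRAP count was 422.

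With all libraries kept under their labels, part of the photosynthesis and ribosomal protein genes were lower at 6 h in the seedlings that had been heated. Of 25 light harvesting and Rubisco genes 4 rose, 15 fell and 6 did not pass the test (5 up and 16 down adjusted over the list alone, camera adjusted p = 9.47e-11, and adjusted p = 0.149 with an estimated correlation) in total mRNA. In TRAP mRNA 15 fell and 10 did not pass the test (5 up and 16 down adjusted over the list alone, camera adjusted p = 1.28e-15), and LHCB2.1 (AT2G05100) stood at -2.44 ± 0.18 and -2.24 ± 0.19 in the 2 kinds of RNA. Of 42 ribosomal protein genes 23 fell and 19 did not pass the test in total mRNA (37 adjusted over the list alone, camera adjusted p = 2.80e-21, and adjusted p = 0.149 with an estimated correlation) and as many did in TRAP mRNA, 23 and 19 (40 adjusted over the list alone, camera adjusted p = 9.13e-23, and adjusted p = 0.0670 with an estimated correlation). Of 28 clock genes 5 rose, 8 fell and 15 did not pass the test (7 up and 10 down adjusted over the list alone, camera adjusted p = 0.0933) in total mRNA. In TRAP mRNA 5 rose, 10 fell and 13 did not pass the test (6 up and 12 down adjusted over the list alone, camera adjusted p = 0.0113, and adjusted p = 0.214 with an estimated correlation). CCA1 was at -1.84 ± 0.28, PRR9 (AT2G46790) at -3.41 ± 0.47 and LNK4 (AT5G06980) at -2.88 ± 0.27 in total mRNA, and RVE2 (AT5G37260) at 1.60 ± 0.14. The adjusted p of these genes was at most 2.10e-04 for CCA1 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The edgeR quasi-likelihood test called 0 of 16 small heat shock protein genes in either kind of RNA (2 in total and 2 in TRAP mRNA at an unadjusted p below 0.05), and DESeq2 also called 0. Their median was -0.32 in total mRNA, although the camera test, which ranks moderated statistics, pointed up (camera adjusted p = 0.0192, and adjusted p = 0.502 with an estimated correlation). In all 1296 genes differed in total mRNA (468 up, 828 down) and 1105 in TRAP mRNA (414 up, 691 down). Single libraries moved these counts, to 449 without heat replicate 1 and 2535 without control replicate 2 in total mRNA, and to 416 without heat replicate 2 and 2611 without control replicate 2 in TRAP mRNA.

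These 6 h values depend on a single control pair. The list counts of light harvesting, ribosomal protein and clock genes above include this pair and are not given without it. The library labelled 6 h control replicate 2 correlated with its own group at 0.853 in total mRNA and 0.879 in TRAP mRNA over 2000 variable genes, and with the 3 h heat group at 0.978 and 0.987. Without it and the TRAP 3 h control replicate 1, 2614 genes differed at 6 h in total mRNA and 4384 in TRAP mRNA. Of the 16 small heat shock protein genes 11 rose and 1 fell at 6 h in total mRNA without them and 11 rose in TRAP mRNA (as many adjusted over the list alone), with medians of 3.21 and 2.96. Of the 28 large chaperones 5 rose and 12 fell in total and 5 rose and 16 fell in TRAP mRNA (13 and 17 down adjusted over the list alone, the same numbers up). HSP17.6B-CI, at -0.36 ± 0.82 and -0.23 ± 0.87 with all libraries and not called, was at 3.46 in total and 3.69 in TRAP mRNA without them (adjusted p = 2.92e-14 and 4.09e-11, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). HSP70-4 was at 1.55 and 1.73 and HSP101 at 1.27 and 1.16 (adjusted p at most 0.00872 for HSP101, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). PRR9 at -3.54 and -2.42, CCA1 at -1.49 and -1.20 and LNK4 at -2.67 and -2.31 were lower without those libraries too. At 3 h 419 genes differed in total mRNA without them.

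**Figure D4:**
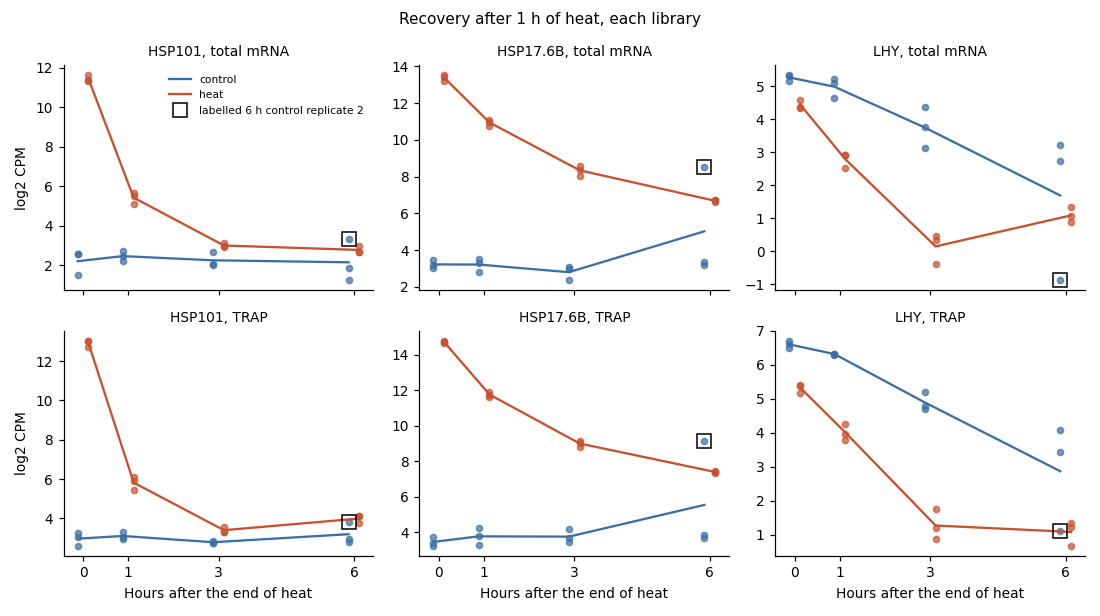
Expression of HSP101, HSP17.6B-CI and LHY as log2 CPM against hours of recovery, in total mRNA and TRAP mRNA. Each point is 1 library, lines join group means of heat and control, and boxes mark the library labelled 6 h control replicate 2, which is part of the mean line.

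The change of the effect over recovery was tested directly as the 6 h effect minus the 0 h effect. Every large chaperone and every small heat shock protein gene had fallen back in both kinds of RNA, 28 of 28 and 16 of 16 in total mRNA and 28 and 16 in TRAP mRNA (as many adjusted over the list alone). All 12 glucosinolate genes had come back up in total mRNA (12 adjusted over the list alone, camera adjusted p = 1.66e-10). HSFA2 differed by -11.25 ± 1.16 between the 2 times in total mRNA and HSP101 by -8.97 ± 0.52. Their adjusted p was at most 5.96e-08 for HSFA2 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With 1 replicate number left out these differences ran from -12.2 to -10.0 and from -9.64 to -8.21. The values and list counts of this test include the libraries labelled 6 h control replicate 2. In all 6300 genes differed in total mRNA, 3982 without replicate 1, and 7128 in TRAP mRNA, 4205 without replicate 3. Between the fractions, 426 genes differed in recovery effect at 0 h in the fit without a replicate block, 76 higher in TRAP mRNA and 350 lower. Without replicate 1, 2 and 3 in turn 196, 122 and 131 did, and 840 without the doubted libraries. CCA1 stood at -1.86 ± 0.25 and TOC1 at -1.31 ± 0.20 (adjusted p = 5.05e-06 and 3.28e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The share higher in TRAP mRNA was 17.84%, and 30.9% with RLE scaling, 38.1% with DESeq2 and 28.7% without a filter on low counts. At 1 h 3 genes differed, named after their values were seen: SR30 (AT1G09140), a serine-arginine splicing factor, at 1.57 ± 0.27, the Aha1 domain gene AT3G12050 at -1.03 ± 0.20 and the T-complex protein 11 gene AT4G09150 at -1.04 ± 0.17. The calls of AT3G12050 and AT4G09150 were lost when any 1 of the 3 replicate numbers was left out and that of SR30 without replicate 1 or 3, in fits with fewer samples that left the folds from -1.19 to -0.94, -1.12 to -0.95 and 1.52 to 1.61. With RLE scaling and without organelle genes AT3G12050 stood at -1.004 ± 0.20 and -0.99 ± 0.20, little changed, with an adjusted p just past the threshold (0.0528 and 0.0683, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The share higher in TRAP mRNA was 33.3%, and 50.0% with RLE scaling, 50.0% without organelle genes and 54.5% of 11 genes with DESeq2. The numbers paired the libraries at 1 h, and with the replicate number as a block 93 genes differed. At 3 h and 6 h the edgeR quasi-likelihood test without a replicate block called 0 genes, with 2019 and 610 at an unadjusted p below 0.05. DESeq2 called 0 at both. Without a filter on low counts, or with the replicate number as a block, genes were called at both times, with the counts given further on.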

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

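The tests of the libraries labelled 6 h control replicate 2, the splits over pairs of libraries, the setting without organelle genes and the thinning to equal depth were chosen after the data were seen, and the thinning was rerun with binomial draws after a first method had been found to add spread. Each number in this paragraph counts genes whose effect differed between groups by the test of that difference. The heat effect varied with time of day for 767 genes in total mRNA and 1484 in TRAP mRNA. It differed between TRAP and total mRNA for 1396, 652, 956, 1023, 702, 588, 434 and 365 genes at ZT48 to ZT69, for 7928 on average over the day, and for 426 and 3 at 0 h and 1 h of recovery. The 6 h effect differed from the 0 h effect for 6300 and 7128 genes in total and TRAP mRNA, and the rhythm after heat from that of controls for 1026 and 1785.

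Other splits of the same samples were drawn and counted, 100 for each result of this paragraph. Here and in the next paragraph the number of splits as large includes the real one. Chance can be excluded for the mean heat effects: 1 split gave as many as 17138 genes in total mRNA (highest other 1) and 1 as many as 17629 in TRAP mRNA (highest other 2). The same holds for rhythms of controls, where 1 and 1 splits were as large as 10671 and 12893 (highest other 464 and 2333). It holds for rhythms of heated seedlings too, with 1 and 1 as large as 8832 and 10222 (highest other 2 and 410). Tests of a difference between heat effects are not settled in this way. A split that exchanges heat and control carries the heat effect itself into the difference or the spread. No conclusion is drawn from the counts that follow. For the mean difference between fractions 1 split was as large as 7928 (highest other 2567). For heat by time of day in total mRNA 2 were as large as 767 (highest other 1001). In TRAP mRNA 1 was as large as 1484 (highest other 1122). For the difference in rhythm 1 and 1 were as large as 1026 and 1785 (highest other 377 and 14). For the 6 h against the 0 h effect 4 and 4 splits were as large as 6300 and 7128. The highest other, 7201 and 8079, lay above the real counts.

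Chance cannot be excluded in this way for the difference between fractions at single times. Of 100 splits each, 26, 35, 26, 38, 35 and 33 were as large at ZT48, ZT51, ZT54, ZT63, ZT66 and ZT69, against real counts of 1396, 652, 956, 588, 434 and 365 and with up to 15125, 15108, 14358, 13489, 12895 and 13300 genes. In recovery 21 and 20 of 100 were as large at 0 and 1 h, against real counts of 426 and 3 and with up to 12741 and 7561 genes. At 3 h and 6 h the real count was 0, which all of the 100 splits reach by construction, so they decide nothing there. The high counts of other splits point to a structure of the samples: a split that exchanges heat and control within 1 fraction carries the heat effect itself. These splits also left aside that the numbers paired total and TRAP libraries at ZT51, ZT54, ZT63 and 1 h of recovery. Drawn over whole pairs, in the fit with the replicate number as a block, there were 10 splits, too few for a share under 0.05. The real split then gave 1289, 1793, 1037 and 93 genes and the highest other 0, 0, 1 and 0. Heat against control with 3 libraries each allows 10 splits, too few for a share under 0.05. In total mRNA the real split gave 12280, 11995, 10942, 10109, 9365, 9345 and 9083 genes at ZT48, ZT51, ZT54, ZT60, ZT63, ZT66 and ZT69, and the highest other 0, 372, 0, 5, 150, 1103 and 2. In TRAP mRNA it gave 12682, 12565, 12363, 11937, 11866, 10821 and 11662 at ZT48, ZT51, ZT54, ZT57, ZT63, ZT66 and ZT69, and the highest other 193, 80, 1, 1, 72, 1 and 300. At 0, 1, 3 and 6 h of recovery it gave 9462, 3981, 229 and 1296 in total mRNA (highest other 0, 0, 0 and 168) and 10236, 5038, 1325 and 1105 in TRAP mRNA (highest other 0, 0, 0 and 283). The comparisons with a group of 2 libraries, at ZT57 and ZT60, were not tested by splits. Where the numbers paired heat and control libraries, at ZT51 in total and TRAP mRNA and at ZT66 in TRAP mRNA, the other splits that part all 3 pairs gave at most 0, 0 and 1 genes, and those that part 1 pair at most 372, 80 and 0.

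The libraries labelled 6 h control replicate 2 carried heat-recovery transcripts. Genes were picked that separated the 3 h heat group from the other 6 h controls, a contrast of heat and time of day together. Those lower in the heat group, called fallen here, had moved a median share of 0.999 (25 genes) of the way to it in total mRNA. In TRAP mRNA the share was 1.00 (29 genes). Those higher in the heat group, called risen, had moved 1.14 (18 genes) and 1.06 (28 genes) in total and TRAP mRNA. A small share of mixed-in RNA of heated plants would leave the fallen genes near the control level, and the higher of their 2 median shares was 1.00. An exchange with a 6 h heat library would bring the correlation with the 6 h heat group above that with the 3 h heat group. It lay below in both kinds of RNA, at 0.949 against 0.978 in total and 0.956 against 0.987 in TRAP mRNA, the smaller gap being 0.0287. Each 6 h heat library correlated best with its own group, at 0.975 or above. A wrong label on the sample is a candidate explanation that the values allow, with 0.999 as the lower median share of the fallen genes and single fallen genes from 0.904 to 1.08, and single risen genes from 0.723 to 1.59; no biological explanation was tested.

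The heat effect on CCA1 and TOC1 was lower in TRAP than in total mRNA. Another scaling or filter left the difference at -1.02 or lower for both genes. Leaving out each replicate number in turn left it at -0.998 or lower. These values argue against the choice among these scalings, or 1 replicate, as the whole cause. They do not bear on scalings that differ more. All of these scalings would remove a shift common to most genes. A difference in ribosome association, which the design names, and other technical explanations, such as reads of unspliced RNA in total mRNA, stay open as not tested.

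Fewer genes were called late in the 24 h cycle in total mRNA, 12280 at ZT48 and 9083 at ZT69. With all libraries thinned to the smallest total the ratio of these counts was 1.07, below the bound of 1.1 set for depth before thinned counts were seen, and 1.07 to 1.08 over 5 further draws, so lower depth late in the cycle is a likely cause. The slope of the fold changes at ZT69 was 0.976 times that at ZT48, which argues against smaller effects, and the coefficient of variation between replicates 0.912 times, which argues against larger spread. The first method of thinning had given 2205 and 1513 genes, a ratio of 1.46 that pointed the other way, and is set aside because it raised the spread of the counts by itself.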

How the results depend on the processing

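The libraries in doubt, the organelle genes and the thinning were settings chosen after the data were seen. Of the values of named genes, only HSP17.6B-CI at 6 h of recovery, not called with all libraries, changed direction under the settings run. From -0.36 in total and -0.23 in TRAP mRNA it went to 0.13 and 0.22 with the replicate number as a block and to 3.46 and 3.69 without the doubted libraries. With single libraries left out it ran from -0.90 to 3.46 and from -0.79 to 3.70, the higher value without control replicate 2 in both. The median of the small heat shock protein genes went with it, from -0.32 to 3.21 in total mRNA without the doubted libraries. The share of called genes that were higher crossed an even split under other settings in several comparisons, among them the difference between fractions on average, at ZT48, ZT54, ZT63 and 1 h of recovery. Of the values of genes named in the text, 109 of 109 kept direction and call with DESeq2, 109 of 110 with RLE scaling, 110 of 110 without a filter, 75 of 76 without organelle genes, 37 of 39 without the doubted recovery libraries, 71 of 71 without the doubted time-course controls and 449 of 478 with a library or replicate number left out. Of the counts of genes and lists, 52 of 52 stayed within 1.5 times with RLE scaling, 42 of 43 with DESeq2, 15 of 15 without organelle genes, 2 of 2 with controls of ZT48 to ZT69 only and 154 of 217 with a library or replicate number left out. With DESeq2 the fractions differed at 1 h of recovery in 11 genes in place of 3. The counts of list calls leave out the comparisons between fractions at single times and in recovery, and of 6 h against 0 h. Over the mean comparisons and those of heat with control at each time, camera called 316 lists. With an estimated correlation it called 167, all among the former, and without the doubted libraries 323, of which 306 were shared. Fry, which asks only whether the members move on balance 1 way, called 376, of which 304 were shared. Without a filter, with more low-count genes tested, heat varied with time in 1408 genes of total and 2661 of TRAP mRNA, 574 differed at 3 h of recovery in total mRNA, and the fractions differed in 31, 316 and 14 genes at 1, 3 and 6 h. The correlation of the repeated ZT54 effect was then 0.666 in total and 0.689 in TRAP mRNA. The cause of these shifts was not tested.

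With a spread taken from the 2 groups compared alone, a fit with fewer samples, 3 h gave 403 genes and 6 h 254 in total mRNA, and 1, 3 and 6 h gave 7820, 103 and 186 in TRAP mRNA. Without the doubted recovery libraries 3 h and 6 h gave 419 and 2614 in total mRNA, 1 h and 6 h gave 7642 and 4384 in TRAP mRNA, and the fractions differed in 840, 41 and 3 genes at 0, 1 and 6 h. Without the doubted time-course controls they differed in 860 genes at ZT48 and 594 at ZT54. The cause was not tested for either set. Depth limits the counts of called genes: with every total mRNA library thinned to the smallest total, heat gave 5791, 5555, 5424, 4861, 5864, 6118, 5375 and 5421 genes at ZT48 to ZT69.

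Outside the 4 comparisons between fractions with every pair above 0.1, the numbers were not taken to pair total and TRAP libraries. Deviations of same-numbered heat and control libraries correlated above 0.1 in 17 of 46 pairs of the time course and 1 of 24 of recovery, and those of same-numbered total and TRAP libraries in 34 of 49 and 21 of 24. At 3 h and 6 h of recovery 5 of 6 such pairs lay above 0.1, with the lowest at 0.0976 and 0.0633. Heat and control libraries had all 3 pairs above 0.1 at ZT51 in both kinds of RNA and at ZT66 in TRAP mRNA, where the block moved no count by over 1.5 times. Over all times, 36 of 49 libraries of the time course and 23 of 24 of recovery correlated best with their own number in the other kind of RNA. The numbers may therefore pair total and TRAP libraries at the other times too. Counts of the fit without a block would then leave out that pairing. With the replicate number as a block, 40 of 52 counts stayed within 1.5 times. The block moved the difference between fractions to 2546, 1289, 1793, 1777, 1109, 1037, 769 and 796 genes at ZT48 to ZT69 and to 982, 93, 33 and 3 at 0, 1, 3 and 6 h of recovery. With the block HSP70-4 was not called at 3 h of recovery in total mRNA, though its fold stayed at 1.52. Its adjusted p was 0.0702 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). It was the 1 of 110 values of named genes whose call changed with the block, and 318 list calls were made.

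Single replicates and libraries moved other counts; each such fit has fewer samples, and a group left with 1 library is assumed to vary like the others. Without replicate 1, 2 and 3 in turn, heat varied with time in 326, 318 and 450 genes of total and 524, 502 and 1158 of TRAP mRNA, and rhythms differed in 433, 360 and 320 and 716, 609 and 819. The fractions differed in 513, 340 and 1173 at ZT48, 231, 304 and 245 at ZT51, 291, 456 and 418 at ZT54, 558, 268 and 362 at ZT57, 224, 210 and 327 at ZT60, 170, 195 and 293 at ZT63, 148, 174 and 130 at ZT66 and 106, 76 and 192 at ZT69. They differed in 196, 122 and 131 genes at 0 h of recovery and 0, 2 and 0 at 1 h. The 6 h effect differed from the 0 h effect in 3982, 4280 and 5192 genes of total and 6223, 4934 and 4205 of TRAP mRNA. At 3 h the total mRNA count was 104, 91 and 164 without control replicate 1, 2 and 3, and 173, 78 and 129 without heat replicate 1, 2 and 3. In TRAP mRNA at 3 h it was 422, 3848 and 2653 without control replicate 1, 2 and 3, and 699, 293 and 412 without heat replicate 1, 2 and 3. At 6 h in total mRNA it was 511, 2535 and 588 without control replicate 1, 2 and 3, and 449, 551 and 782 without heat replicate 1, 2 and 3. In TRAP mRNA at 6 h it was 498, 2611 and 486 without control replicate 1, 2 and 3, and 445, 416 and 449 without heat replicate 1, 2 and 3.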

Other observations

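The comparison of controls at neighbouring times and 24 h apart, and the search for heat-induced transcripts in control libraries, were chosen after results had been seen. At 6 h of recovery the lowest genes included PCC1 (AT3G22231), a gene under pathogen and circadian control, at -5.83 ± 0.99 in total and -5.72 ± 1.23 in TRAP mRNA (log2 fold change ± SE). AT1G26390, of the berberine bridge enzyme family, stood at -5.40 ± 0.98 and -6.21 ± 1.16, the plant defensin gene PDF1.2c (AT5G44430) at -5.11 ± 1.103 in total mRNA and LURP1 (AT2G14560), a gene of the defence against downy mildew, at -5.49 ± 0.92 in TRAP mRNA. Without the libraries labelled 6 h control replicate 2 and the TRAP 3 h control replicate 1, PCC1 was at -6.41 and -6.28, AT1G26390 at -5.96 and -6.79, PDF1.2c at -5.66 in total and LURP1 at -5.99 in TRAP mRNA. PCC1 in TRAP mRNA was not called without control replicate 1 (-4.65) or heat replicate 2 (-5.37) or 3 (-5.01), and PDF1.2c not without control replicate 3 (-2.80) or heat replicate 1 (-5.42) or 2 (-4.82). The highest included WNK9 (AT5G28080), a WNK family kinase gene, at 2.05 ± 0.37 in total mRNA. The adjusted p of these genes was at most 0.0130 for PDF1.2c with all libraries (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

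The control libraries also held strong waves outside the clock list. COL2 (AT3G02380), a B-box gene, had a log2 amplitude of 1.85 in total and 2.47 in TRAP mRNA, with its peak at 0.377 and 0.0549 h after subjective dawn. PHS2 (AT3G46970), a cytosolic glucan phosphorylase, had 1.43 with its peak at 11.1 h in total mRNA, and LDOX (AT4G22880), an enzyme of anthocyanin synthesis, 2.46 at 21.9 h. MYBL2 (AT1G71030), a repressor of that pathway, had 2.21 at 6.34 h, and the chloroplast sigma factor gene SIGE (AT5G24120) 1.44 at 0.249 h. In TRAP mRNA AMY3 (AT1G69830), an alpha-amylase, had 1.42 at 8.95 h and BT2 (AT3G48360), a BTB and TAZ domain gene, 1.55 at 13.0 h. The adjusted p of these waves was at most 2.77e-23 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). For LDOX the wave after heat had an amplitude of 2.48, and its rhythm was not called different (adjusted p = 0.898, same test), which does not show that it was equal.

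Controls at neighbouring times differed by uneven numbers of genes. In total mRNA the numbers ran from 138 between ZT69 and ZT72 to 1290 between ZT51 and ZT54, with 1062 between ZT63 and ZT66. In TRAP mRNA they were 315, 1636 and 1625 at these steps, again the lowest, the highest and the step at ZT63 to ZT66 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Between ZT72 and ZT48, the same time on the next day, 1691 genes were higher and 1013 lower in total mRNA, and 1245 higher and 828 lower in TRAP mRNA.

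Among the controls of the time course, heat-induced transcripts stood above their groups in total mRNA at ZT54 replicate 2 (2.18% of the heat level as the median over 117 genes) and ZT48 replicate 1 (0.316%). Replicate 3 at ZT48 was at 0.120%, with HSP101 at 21.8 CPM where replicates 1 and 2 had 26.3 and 7.99, and it was kept in the setting without the doubted controls. In TRAP mRNA, over 129 genes, they did so at ZT69 replicate 2 (0.435%), ZT54 replicate 2 (0.334%), ZT48 replicate 1 (0.244%) and ZT57 replicate 2 (0.227%). At ZT48 and ZT54 the same replicate number stood out in both kinds of RNA.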
